A study of Homo sapiens with 26 samples.

How the data were processed

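RNA of 26 samples of 3 lung cancer cell lines was hybridised to single-colour, biotin-labelled arrays with transcript cluster probe sets. The deposited values are on the log2 scale. RMA and Partek are named in the submitters' processing notes, without versions, and RMA corrects background, applies quantile normalization and summarises probes. Whether all arrays were normalized together is not given in the sources used here. The table held features with values between 1.35 and 19.91 and no missing value. That range is wider than is usual for RMA values, so a further scaling step cannot be excluded. Of the features, 17709 had 1 gene symbol, all matched to a reference gene by Entrez ID, 0 had several and 6642 had none. The symbols belonged to 17687 genes, and for the 20 genes with over 1 probe set the one with the highest mean was used. Detection calls were not used here. The 63 spike-in control features had a median of 3.22 and the 23 background probe sets means between 2.34 and 6.69, which bounds how far values of dim genes can be read. No genome build is named, and no coordinates are given.

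Groups came from the sample labels, 6 in all. The labels say biological replica, and nothing else says that arrays came from separate cultures, so p-values measure only the spread between these arrays, which can be technical. No pair of arrays of a group was identical. The SD of the difference between 2 arrays of a group had a median of 0.486 over 9 pairs of the same run and 0.58 over 36 pairs of different runs.

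The sorted values of each whole array were clustered without labels (average linkage, 3 clusters). The clusters held 9, 10 and 7 arrays with mean values of 7.08 to 7.12, 7.3 to 7.36 and 6.94 to 6.99, and are called normalization runs here. Every run held all 3 lines and both treatments, except that A549 had no Omomyc array in run 3.

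limma 3.58.1 in R 4.3.3 (statmod 1.5.0) fitted 1 coefficient per group to all 26 arrays with lmFit and eBayes, without a block, leaving 20 residual degrees of freedom. Contrasts were Omomyc minus PBS in each line, their average, and the 2 interaction contrasts in a moderated F test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Calls were compared between lines with the overlap of independent lists and Fisher's exact test; the lines share no control arrays. The 35 gene lists fixed before the data were examined held 1042 distinct genes, of which 918 were measured, and camera tested them at a preset correlation of 0.01. In each line the named genes are the 12 with the largest and the 12 with the smallest fold change among called genes whose mean in 1 of the line's groups was above the median of all genes. The same number was taken for the average. Up to 4 members of each list (2 that rose and 2 that fell with the smallest p, or 2 where none passed), the 10 genes with the smallest F test p and 21 fixed genes were added, of which 18 were measured and the others were not analysed here.

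Same-numbered PBS and Omomyc arrays were checked for pairing by the correlation of their deviations from the group means. It was 0.26 to 0.39 for the 5 pairs of H1299 and 0.11 to 0.2 for the 3 pairs of A549, all over 0.1, so the numbers pair arrays there by the rule set beforehand. Each of these pairs lay in 1 run, and with the run removed the correlations were -0.15 to 0.046 and -0.19 to 0.0083. In H1975 1 of 4 pairs was over 0.1 (-0.2 to 0.33), and pairs 2 and 4 lay in different runs (-0.15 and -0.2). With the run removed the H1975 pairs were at -0.26 to 0.082, so no pair of any line stayed over 0.1. Removing the run by itself lowers correlations between arrays of the same run, so a low value there does not exclude pairing.

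The fit was tested on simulated data with the means and spreads of the 17687 genes and 200 genes changed. For a log2 change of 2 it recovered 98%, 89% and 97% of 100 genes in H1975, A549 and H1299, and for a change of 1 it recovered 51%, 41% and 49%, with 7, 5 and 10 false calls. The simulation held no runs. Alternatives planned were quantile normalization, median centring, leaving out genes under the 30th percentile of mean level, the mean of probe sets, a fit on the line alone, trend and robust settings, no moderation, array weights, the replicate block, an adjusted p under 0.01, a fold change of at least 2, leaving out each array, and for the lists an estimated correlation and fry. The run as a block, each run alone, the run with an estimated correlation, the run together with the replicate block, and exchange within pairs for the G1-S difference were chosen after seeing the data.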

Results

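Gene expression was measured on 26 single-colour microarrays of 3 human lung cancer cell lines grown with either Omomyc or its vehicle, phosphate-buffered saline (PBS). Omomyc is a miniprotein derived from the dimerization domain of the transcription factor MYC that competes with MYC for its partner MAX and for DNA. It was added to the medium as protein at 12.8 µM, and the time of exposure is not given in the sources used here. NCI-H1975 (H1975) had 4 PBS and 5 Omomyc arrays, A549 had 4 and 3, and NCI-H1299 (H1299) had 5 and 5. The comparisons ask which transcripts change with Omomyc in each line and whether the lines differ in this. The labels describe the arrays of a group as biological replicas. The deposited log2 values named 17687 genes, and all were tested. Changes are log2 fold changes, Omomyc minus PBS, with the standard error of the limma fit after ±, and adjusted p is Benjamini-Hochberg. Each list of genes was fixed beforehand, its counts adjusted over the list alone name rising and then falling members, and its median is a log2 fold change. The number of arrays limits the precision. PBS was the only control, so in every comparison an effect of Omomyc and a response to any added protein cannot be told apart. The NRF2 target genes AKR1B10 and AKR1C1, which are high in KEAP1-mutant A549 cells, checked the line labels. AKR1B10 was at 17.10 ± 0.22 (SD, n = 4) in A549 PBS arrays, at 3.75 ± 0.27 (n = 4) in H1975 and at 3.00 ± 0.41 (n = 5) in H1299. AKR1C1 was at 16.73 ± 0.24, 9.37 ± 0.33 and 4.36 ± 0.75.

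Clustering of the distributions of values, cut at 3 clusters, parted the arrays into sets of 9, 10 and 7, called normalization runs here. No label names them, so separate normalization cannot be told apart from other kinds of batch. The run carried 97.3% of the first principal component of the residuals. A549 had no Omomyc array in run 3. The counts of called genes, and the list tests with an estimated correlation, are therefore also given with the run as a block, an alternative chosen after seeing the data. Where 2 adjusted p follow with an estimated correlation, the second has the run as a block too. Where a line had a single array of a treatment in a run, a fit on that run alone took the spread from other groups, so that array is assumed to vary as they do. This was so in H1975 for PBS in run 1 and both treatments in run 3, and for both treatments in run 2 of A549 and run 1 of H1299.

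In H1975, Omomyc was followed by higher levels of ATF4 and integrated stress response genes and lower levels of DNA replication genes. The call of the DNA replication list was lost with an estimated correlation (adjusted p = 0.254), and not with the run as a block too (adjusted p = 0.00326). Among genes above the median level, the largest rises were those of IL24, a cytokine gene, by 6.40 ± 0.35 (adjusted p = 4.81e-13), and GDF15, a stress-induced cytokine of the TGF-beta family, by 5.23 ± 0.40 (adjusted p = 3.04e-10). DDIT3, which encodes the stress transcription factor CHOP, rose by 4.61 ± 0.25 (adjusted p = 4.13e-13). LTF (4.36 ± 0.33), NR4A1 (4.34 ± 0.54), EPOR (4.11 ± 0.25), and PRSS8 (3.74 ± 0.35) followed. The dual-specificity phosphatase gene DUSP1 (3.56 ± 0.48), SERPINB4 (3.54 ± 0.24), SIK1 (3.50 ± 0.31), PIM1 (3.39 ± 0.32) and ADM (3.38 ± 0.31) came next. The largest falls were those of SLITRK6 (-5.34 ± 0.27, adjusted p = 1.49e-13), the growth factor gene BMP4 (-5.15 ± 0.29, adjusted p = 4.81e-13) and DIO2, a deiodinase gene (-4.50 ± 0.27, adjusted p = 2.39e-12). FAM111B (-3.92 ± 0.27), CYP4X1 (-3.70 ± 0.22), NANOS1 (-3.58 ± 0.43), the integrin gene ITGB8 (-3.36 ± 0.34) and NCOA5 (-3.19 ± 0.22) fell. So did TNFRSF11B (-3.10 ± 0.30), LYPD1 (-3.02 ± 0.33), CAVIN2 (-2.99 ± 0.23) and CD14 (-2.91 ± 0.33). Background probe sets reached 6.69, and for the called genes IL24, DDIT3, LTF, NR4A1, EPOR, PRSS8, SERPINB4, SIK1, SLITRK6, DIO2, FAM111B, CYP4X1, NANOS1, ITGB8, NCOA5, TNFRSF11B, LYPD1 and AKR1C2 the mean of the lower group did not exceed that level, so their folds, and their order by fold, are uncertain. In all, 2095 genes passed the threshold, 985 higher and 1110 lower, and 1386 higher and 1105 lower with each array centred on its median. With the run as a block 3400 passed, among them all 2095. With the replicate block added to the run, 1245 passed, though by the correlation check the replicate numbers do not pair the arrays of this line. On the arrays of run 1, 2 or 3 alone 1018, 1047 and 780 genes passed, run 3 setting 1 array against 1. Of 115 named genes called here 22 lost the call when some 1 array was left out, among them PSPH and MNT.

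Of the ATF4 and integrated stress response genes in H1975, 20 of 29 measured members rose and 1 fell (21 and 1 adjusted over the list alone, median 1.15, camera adjusted p = 2.2e-20, adjusted p = 0.0115 and 1.06e-05 with an estimated correlation). The amino acid transporter gene SLC7A11 rose by 2.01 ± 0.28 and ALDH1L2, of mitochondrial folate metabolism, by 2.41 ± 0.24, while the serine synthesis gene PSPH fell by 0.97. The list medians in runs 1, 2 and 3 were 1.17, 1.40 and 1.36. Among DNA replication and G1-S genes, 0 of 41 measured members rose and 22 fell (0 and 24 adjusted over the list alone, median -1.09, camera adjusted p = 8.61e-17, adjusted p = 0.254 and 0.00326 with an estimated correlation). UHRF1, a maintenance methylation factor, changed by -2.57 ± 0.25 and the helicase subunit gene MCM3 by -2.24 ± 0.24, and the medians in the 3 runs were -1.25, -0.88 and -1.25. In the G2-M and mitosis list, 2 of 44 measured members rose and 1 fell (2 and 1 adjusted over the list alone, median 0.032, camera adjusted p = 0.535, adjusted p = 0.908 and 0.819 with an estimated correlation). For the unfolded protein response of the endoplasmic reticulum (ER), 10 of 23 measured members rose and 0 fell (13 and 0 adjusted over the list alone, median 0.56, camera adjusted p = 1.32e-08, adjusted p = 0.0568 and 0.00042 with an estimated correlation). HERPUD1 rose by 1.91 ± 0.21 and the co-chaperone gene DNAJB9 by 1.83 ± 0.23, with run medians of 0.93, 0.50 and 0.39.

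Hypoxia targets in H1975 shifted up, 9 of 20 rising and 1 falling (11 and 2 adjusted over the list alone, median 0.58, camera adjusted p = 2.9e-05, adjusted p = 0.26 and 0.00209 with an estimated correlation), with ADM at 3.38 ± 0.31 and NDRG1 at 2.01 ± 0.28. Of the genes described as repressed by MYC, 10 of 29 rose (12 and 1 adjusted over the list alone, median 0.31, camera adjusted p = 0.00039, adjusted p = 0.26 and 0.0332 with an estimated correlation), among them GADD45A (2.52 ± 0.22), DUSP1 and CDKN1A (1.63 ± 0.30), the gene of the cell-cycle inhibitor p21. Hallmark-type MYC targets had 9 falling and 6 rising members of 72 (7 and 14 adjusted over the list alone, median -0.19, camera adjusted p = 0.0311, adjusted p = 0.756 and 0.455 with an estimated correlation). The nucleolar and ribosome biogenesis targets had 8 of 62 falling and 2 rising (2 and 8 adjusted over the list alone, median -0.078, camera adjusted p = 0.051, adjusted p = 0.772 and 0.451 with an estimated correlation), and at the preset correlation they were called with the run as a block (adjusted p = 0.0426). Their medians in the 3 runs were -0.34, 0.081 and -0.25, run 2 going the other way, and the median was -0.0059 with each array centred on its median. SRSF1 (-1.66 ± 0.22), SLC19A1 (-1.53 ± 0.21), POLR1A (-1.12 ± 0.20) and UTP14A (-0.93 ± 0.19) fell, whereas the hexokinase gene HK2 rose by 2.04 ± 0.32. In glycolysis 6 of 20 rose (7 and 1 adjusted over the list alone, median 0.23, camera adjusted p = 0.00398, adjusted p = 0.555 and 0.249 with an estimated correlation). In the translation list 12 rose and 2 fell (12 and 3 adjusted over the list alone, median 0.043, camera adjusted p = 0.00398, adjusted p = 0.364 and 0.249 with an estimated correlation), the tRNA synthetase gene AARS1 at 1.26 ± 0.15 being its example. Heat shock genes fell in 4 of 20 cases (0 and 4 adjusted over the list alone, median -0.38, camera adjusted p = 0.00945, adjusted p = 0.451 and 0.118 with an estimated correlation), including DNAJA1 (-1.53 ± 0.24). Ribosomal protein genes had a camera call with 0 members past the threshold (0 and 0 adjusted over the list alone, median 0.26, camera adjusted p = 0.00122, adjusted p = 0.657 and 0.484 with an estimated correlation). The call of ribosomal protein genes was lost without PBS replicate 3 (adjusted p = 0.0792). That of hallmark-type MYC targets was lost without PBS replicate 1 (adjusted p = 0.111), PBS replicate 4 (0.0511), Omomyc replicate 2 (0.08) or Omomyc replicate 5 (0.0717), and with the replicate block (adjusted p = 0.0749).

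In A549, genes of the endoplasmic reticulum (ER) stress response were among the largest rises, and more genes were higher than lower. CRELD2, an ER stress-inducible protein gene, rose by 4.29 ± 0.33 (adjusted p = 4.15e-09), SDF2L1 by 3.00 ± 0.47 (adjusted p = 0.000449) and the secreted ER stress factor gene MANF by 2.76 ± 0.27 (adjusted p = 5.81e-07). HID1 (2.88 ± 0.36), the keratin gene KRT4 (2.81 ± 0.29), EML2-AS1 (2.69 ± 0.39), and FICD (2.59 ± 0.28) were higher. Further rises were those of DNAJB9 (2.48 ± 0.26), the coat protein gene SEC24D (2.42 ± 0.37), the ER ubiquitin ligase gene SYVN1 (2.39 ± 0.29), NUCB2 (2.36 ± 0.24) and ERO1B (2.30 ± 0.31). Among genes above the median level, the largest falls were CXCL8 (-2.27 ± 0.52), the inhibitor of differentiation gene ID3 (-2.16 ± 0.39), JUNB (-2.08 ± 0.46), PMEPA1 (-2.04 ± 0.35) and ID1 (-1.98 ± 0.34). They were followed by the metalloproteinase genes MMP7 (-1.93 ± 0.31) and MMP2 (-1.60 ± 0.28), HHIP (-1.90 ± 0.37), PRG4 (-1.76 ± 0.35), MYEOV (-1.54 ± 0.36), RASSF2 (-1.48 ± 0.37) and ABCG1 (-1.41 ± 0.22). The adjusted p of these falls was at most 0.039. The folds are uncertain in the same way for HID1, CXCL8, MMP2, HHIP, PRG4, ABCG1, CCL20, CTH, LOX, LAMP3 and TXNIP. In all, 211 genes passed, 162 higher and 49 lower. With the run as a block 502 passed, among them all 211. Runs 1 and 2 alone gave 50 and 44, run 2 setting 1 array against 1. The share of higher genes was 76.8%, against 66.2% (233 higher and 119 lower) after quantile normalization of all arrays, and the run as a block gave 303 higher and 199 lower. The count was 128 without Omomyc replicate 1 and 139 without PBS replicate 4. Of 40 named genes called here 15 lost the call when some 1 array was left out: ALDH1L2, ALDOC, CCNE1, CTH, CXCL8, HHIP, JUNB, LAMP3, MYEOV, P4HA2, PRG4, RASSF2, SNAI2, TXNIP and TYMS. Without PBS replicate 3 alone CXCL8 was at -1.52 (adjusted p = 0.0624), MYEOV at -1.39 (adjusted p = 0.081) and RASSF2 at -1.38 (adjusted p = 0.101).

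ER unfolded protein response genes in A549 moved together: 19 of 23 measured members rose and 0 fell (21 and 0 adjusted over the list alone, median 1.62, camera adjusted p = 1.26e-65, adjusted p = 2.44e-07 and 1.35e-10 with an estimated correlation). The run medians were 1.59 and 1.59. Cholesterol and fatty acid synthesis genes had 6 of 27 rising (11 and 0 adjusted over the list alone, median 0.63, camera adjusted p = 4.05e-11, adjusted p = 0.125 and 0.000508 with an estimated correlation), with the sterol synthesis genes LSS at 1.53 ± 0.28 and MSMO1 at 1.12 ± 0.21. TGF-beta and SMAD targets had 5 of 21 falling (0 and 9 adjusted over the list alone, median -0.69, camera adjusted p = 1.78e-10, adjusted p = 0.0793 and 7.39e-05 with an estimated correlation), and the run medians were -0.61 and -0.60. In the immediate early list 1 of 28 fell (0 and 7 adjusted over the list alone, median -0.49, camera adjusted p = 1.02e-08, adjusted p = 0.367 and 0.105 with an estimated correlation), and PBS replicate 3 stood at a list mean of 11.81 while the other 3 PBS arrays lay between 8.914 and 9.258. Without PBS replicate 3 the list median was -0.0471 in place of -0.49 (camera adjusted p = 0.00624, adjusted p = 0.734 with an estimated correlation). With all arrays the medians in runs 1 and 2 were -0.28 and -2.17, and PBS replicate 3 was the only PBS array of A549 in run 2. NF-kB genes had 2 of 29 falling (1 and 3 adjusted over the list alone, median -0.28, camera adjusted p = 0.00746, adjusted p = 0.636 and 0.0397 with an estimated correlation), CCL20 at -2.23 ± 0.41. DNA replication genes had 1 of 41 falling (0 and 1 adjusted over the list alone, median -0.29, camera adjusted p = 0.000155, adjusted p = 0.666 and 0.0748 with an estimated correlation), CCNE1, the cyclin E1 gene, at -1.16 ± 0.26, and G2-M genes 0 of 44 (0 and 0 adjusted over the list alone, median -0.25, camera adjusted p = 0.000578, adjusted p = 0.713 and 0.107 with an estimated correlation).

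Among MYC target lists in A549, nucleolar genes had 0 of 62 falling (0 and 0 adjusted over the list alone, median -0.084, camera adjusted p = 0.0199, adjusted p = 0.825 and 0.191 with an estimated correlation) and medians of -0.24 and 0.044 in runs 1 and 2, which differ in sign. In the same comparison hallmark-type targets had 1 of 72 falling (0 and 1 adjusted over the list alone, median -0.058, camera adjusted p = 0.133, adjusted p = 0.825 and 0.605 with an estimated correlation). That member was TYMS, the thymidylate synthase gene, at -0.91 ± 0.23 (adjusted p = 0.0402), with an adjusted p of 0.0623 with the replicate block. Genes described as repressed by MYC had 0 rising and 1 falling (0 and 1 adjusted over the list alone, median -0.11, camera adjusted p = 0.0574, adjusted p = 0.666 and 0.191 with an estimated correlation). The ATF4 list had 3 of 29 rising (4 and 0 adjusted over the list alone, median 0.08, camera adjusted p = 0.0819, adjusted p = 0.825 and 0.23 with an estimated correlation), ALDH1L2 at 1.36 ± 0.28 and CTH at 1.27 ± 0.27. Hypoxia targets had 2 rising members (4 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 0.000689, adjusted p = 0.469 and 0.0183 with an estimated correlation), LOX at 1.57 ± 0.29. For mesenchymal genes 1 rose and 2 fell (1 and 3 adjusted over the list alone, median -0.21, camera adjusted p = 0.023, adjusted p = 0.624 and 0.0748 with an estimated correlation). The histone list was called upward with 0 members past the threshold (0 and 0 adjusted over the list alone, median 0.36, camera adjusted p = 0.0417, adjusted p = 0.825 and 0.806 with an estimated correlation), its run medians were -0.34 and 1.06, and its adjusted p was 0.512 with the replicate block and 0.102 with the run as a block. Airway and alveolar markers had 1 of 19 rising (2 and 0 adjusted over the list alone, median 0.18, camera adjusted p = 0.0417, adjusted p = 0.367 and 0.103 with an estimated correlation), LAMP3 at 1.60 ± 0.34. Leaving out 1 array ended the call of mesenchymal genes without PBS replicate 3 (adjusted p = 0.0741) or Omomyc replicate 2 (0.142), and of airway and alveolar markers without PBS replicate 1 (adjusted p = 0.0696), PBS replicate 3 (0.104), Omomyc replicate 1 (0.167) or Omomyc replicate 2 (0.101). It also ended that of nucleolar genes without PBS replicate 1 (adjusted p = 0.0804) or Omomyc replicate 2 (0.13), and of histones without PBS replicate 3 (adjusted p = 0.429), PBS replicate 4 (0.469), Omomyc replicate 2 (0.0845) or Omomyc replicate 3 (0.419).

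In H1299, Omomyc was followed by lower ATF4 and integrated stress response, histone and DNA replication genes and by higher sterol synthesis genes. The call of the histone list was lost with an estimated correlation (adjusted p = 0.0927 and 0.0623). CHAC1, a glutathione-degrading enzyme gene and ATF4 target, was, among genes above the median level, one of those that fell most, at -4.31 ± 0.37 (adjusted p = 9.86e-09), with the histone gene H2BC14 at -4.19 ± 0.45 (adjusted p = 3.51e-07) and SLC7A11 at -3.84 ± 0.26 (adjusted p = 1.19e-10). SPP1 (-3.72 ± 0.33), SESN2 (-3.29 ± 0.25), the amino acid transporter gene SLC7A5 (-3.26 ± 0.16), and STC2 (-2.74 ± 0.22) fell too. The same held for the histone genes H3C8 (-3.02 ± 0.56), H2AC14 (-3.01 ± 0.34), H2BC11 (-2.94 ± 0.31), H2BC8 (-2.70 ± 0.30) and H2AC8 (-2.67 ± 0.38). Values of single histone genes are uncertain, since near-identical copies can share probes. Rises were led by PINLYP (3.21 ± 0.30, adjusted p = 3.85e-08), HMGCS1, an early enzyme gene of cholesterol synthesis (2.95 ± 0.26, adjusted p = 1.57e-08), and the interferon-inducible GBP2 (2.65 ± 0.19, adjusted p = 3.18e-10). ACSS2 (2.57 ± 0.31), BHLHE40 (2.57 ± 0.29), GPNMB (2.53 ± 0.27), and SLCO4C1 (2.47 ± 0.24) followed, then RALGDS (2.47 ± 0.27), SLC17A7 (2.45 ± 0.24), CLEC2B (2.44 ± 0.29), ITGA10 (2.42 ± 0.26) and DACT1 (2.36 ± 0.30). In this line the folds of SPP1, STC2, PINLYP, GPNMB, SLC17A7, DACT1, CTH, CDC45 and CD274 are uncertain for their low level. In all, 1569 genes passed, 770 higher and 799 lower, and 1046 higher and 885 lower with each array centred on its median. With the run as a block 2812 passed, among them all 1569. Runs 1, 2 and 3 alone gave 81, 523 and 1194, run 1 setting 1 array against 1. Of 89 named genes called here 15 lost the call when some 1 array was left out, among them CDK4, MAX, MLX and MXD1.

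The ATF4 list fell in H1299: 1 of 29 measured members rose and 21 fell (1 and 23 adjusted over the list alone, median -1.85, camera adjusted p = 1.53e-36, adjusted p = 0.00039 and 2.5e-07 with an estimated correlation). Its medians in the 3 runs were -1.71, -1.97 and -1.81, and CTH was the member that rose (0.95 ± 0.22). DNA replication genes fell as well: 0 of 41 measured members rose and 31 fell (0 and 36 adjusted over the list alone, median -1.30, camera adjusted p = 5.12e-33, adjusted p = 0.0192 and 0.000136 with an estimated correlation). CDC45 (-2.39 ± 0.28) and MCM6 (-2.22 ± 0.29) had the smallest p among them, and the run medians were -1.13, -1.35 and -1.27. Of the replication-dependent histones 19 of 32 fell (0 and 24 adjusted over the list alone, median -1.32, camera adjusted p = 4.17e-21, adjusted p = 0.0927 and 0.0623 with an estimated correlation), with run medians of -1.95, -1.68 and -0.70. G2-M genes had 6 of 44 falling (0 and 6 adjusted over the list alone, median -0.34, camera adjusted p = 1.3e-05, adjusted p = 0.433 and 0.0736 with an estimated correlation). Cholesterol and fatty acid synthesis moved up: 16 of 27 measured members rose and 0 fell (17 and 0 adjusted over the list alone, median 1.01, camera adjusted p = 4.94e-19, adjusted p = 0.0175 and 2.5e-05 with an estimated correlation); the run medians were 1.14, 0.95 and 1.01. The ER unfolded protein list had 8 of 23 rising (11 and 0 adjusted over the list alone, median 0.54, camera adjusted p = 9.1e-08, adjusted p = 0.0428 and 0.000331 with an estimated correlation), MANF at 1.17 ± 0.22 and CALR at 0.99 ± 0.20.

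MYC target lists were lower in H1299. Hallmark-type targets had 25 of 72 falling and 1 rising (1 and 32 adjusted over the list alone, median -0.56, camera adjusted p = 1.14e-13, adjusted p = 0.12 and 0.00778 with an estimated correlation), with run medians of -0.52, -0.56 and -0.53. Nucleolar and ribosome biogenesis genes had 15 of 62 falling (0 and 25 adjusted over the list alone, median -0.43, camera adjusted p = 8.71e-12, adjusted p = 0.216 and 0.00561 with an estimated correlation), with run medians of -0.57, -0.55 and -0.46, NOP58 at -1.12 ± 0.19 and NIP7 at -0.90 ± 0.17. Nucleotide biosynthesis genes had 12 of 26 falling (1 and 15 adjusted over the list alone, median -0.66, camera adjusted p = 1.19e-10, adjusted p = 0.0927 and 0.00203 with an estimated correlation), TYMS at -1.63 ± 0.19 and the purine synthesis gene PFAS at -1.56 ± 0.18. In the translation list 15 of 28 fell (0 and 18 adjusted over the list alone, median -0.76, camera adjusted p = 5.47e-16, adjusted p = 0.00188 and 0.000517 with an estimated correlation). Its members WARS1 (-1.69 ± 0.15) and AARS1 (-1.34 ± 0.14) encode tRNA synthetases, which are ATF4 targets too. Genes described as repressed by MYC had 1 rising and 4 falling (2 and 5 adjusted over the list alone, median -0.013, camera adjusted p = 0.281, adjusted p = 0.757 and 0.425 with an estimated correlation), and their median was above 0 after median centring.

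**Figure D1:**
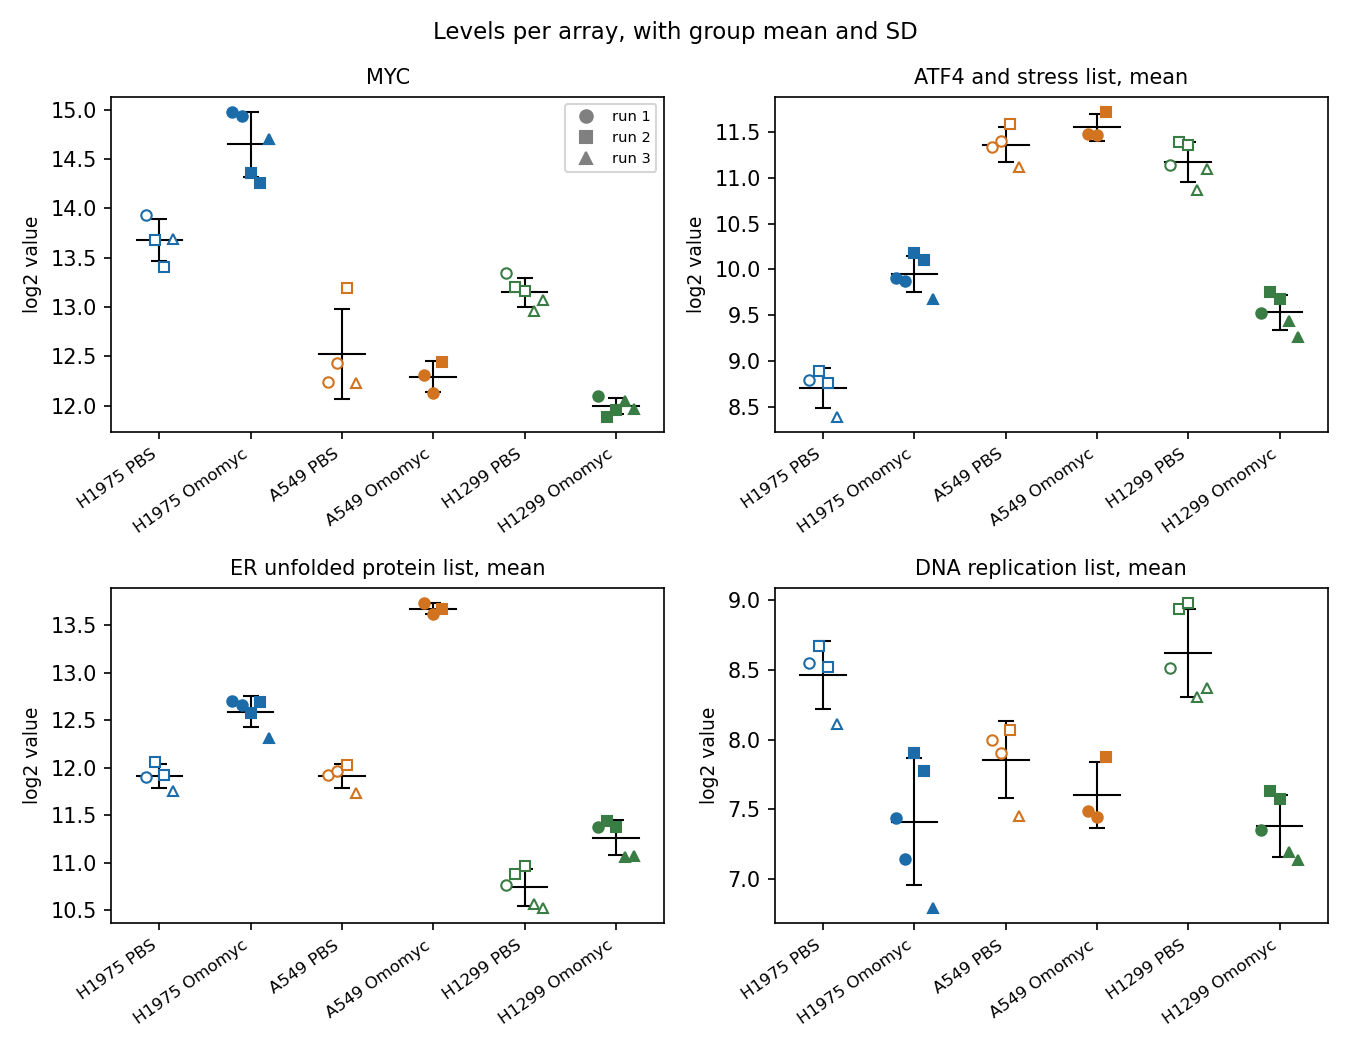
Log2 level per array of MYC and mean log2 level of 3 gene lists in the 6 groups, with open symbols for PBS, filled symbols for Omomyc, shapes for the 3 normalization runs, and bars for the group mean and SD. The ATF4 list is higher with Omomyc in H1975 and lower in H1299, and the ER unfolded protein list is higher with Omomyc in each line.

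MYC transcript itself rose in H1975 by 0.97 ± 0.20 (adjusted p = 0.00119), fell in H1299 by 1.15 ± 0.19 (adjusted p = 0.000135), and was at -0.23 ± 0.23 (adjusted p = 0.915) in A549. The limma F test of the difference between lines gave an adjusted p of 2.07e-05. MAX, the partner of MYC, fell in H1975 (-0.92 ± 0.23) and H1299 (-0.75 ± 0.22) and was at 0.94 ± 0.26 (adjusted p = 0.0804) in A549. Of the MAX-binding antagonists of MYC, MXD1 rose in H1975 (1.32 ± 0.24), fell in H1299 (-0.75 ± 0.23) and was at 1.03 ± 0.27 (adjusted p = 0.0589) in A549. MXI1 rose in H1975 (0.99 ± 0.20) and H1299 (0.75 ± 0.19) and was at -0.06 ± 0.23 (adjusted p = 0.99) in A549. MNT rose in H1975 (0.88 ± 0.28, adjusted p = 0.0382). MLX, another gene of the MYC-MAX-MXD list and not one of these antagonists, rose in H1299 (0.78 ± 0.23, adjusted p = 0.0276). MYCN, MYCL, MXD3 and MGA passed in none of the lines, with changes between -0.51 and 0.34. The MYC-MAX-MXD list had camera adjusted p of 0.152, 0.282 and 0.878 in H1975, A549 and H1299. Of cell-cycle genes, CCND1, the cyclin D1 gene, fell in H1975 (-1.97 ± 0.20) and was at -0.37 ± 0.22 (adjusted p = 0.75) in A549 and -0.14 ± 0.18 (adjusted p = 0.805) in H1299. CDK4 fell in H1299 (-0.68 ± 0.21, adjusted p = 0.0399) and was at -0.16 ± 0.22 (adjusted p = 0.798) in H1975 and -0.09 ± 0.26 (adjusted p = 0.989) in A549. CDKN1A rose in H1975 and in H1299 (1.10 ± 0.28, adjusted p = 0.0121) and was at -0.41 ± 0.34 (adjusted p = 0.879) in A549. The nucleolin gene NCL was at -0.35 ± 0.30 (adjusted p = 0.6), 0.17 ± 0.34 (adjusted p = 0.983) and -0.42 ± 0.28 (adjusted p = 0.484). TXNIP was at -0.75 ± 0.26 (adjusted p = 0.0574), -1.44 ± 0.29 (adjusted p = 0.00728) and 0.28 ± 0.24 (adjusted p = 0.64) in that order.

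**Figure D2:**
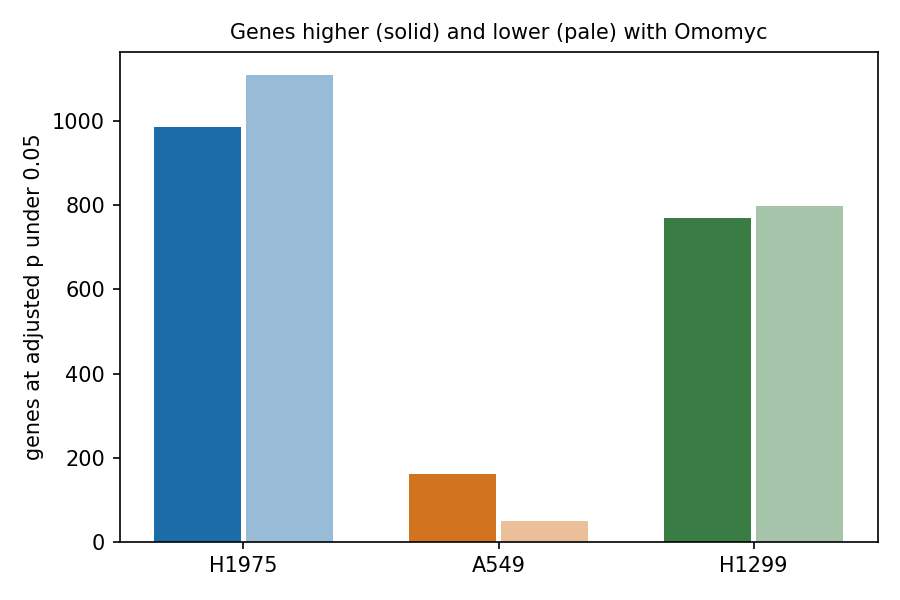
Number of genes at adjusted p under 0.05 that were higher (solid bars) and lower (pale bars) with Omomyc in each line. H1975 had 985 higher and 1110 lower, A549 162 and 49, and H1299 770 and 799.

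Averaged over the lines, ER genes were higher and replication genes lower. Sterol genes were higher at the preset correlation, a call lost with an estimated correlation and not with the run as a block too. The ER unfolded protein list had a median of 0.88 (camera adjusted p = 2.62e-35, adjusted p = 3.19e-05 and 2.94e-08 with an estimated correlation). The cholesterol list was at 0.62 (camera adjusted p = 2.67e-13, adjusted p = 0.0713 and 0.000181 with an estimated correlation) and the DNA replication list at -0.87 (camera adjusted p = 1.32e-33, adjusted p = 0.0356 and 0.000171 with an estimated correlation). In H1975 alone the cholesterol list was not called, with a median of 0.253. Its members passed in both directions there, INSIG1 and MSMO1 rising and ACACA and ELOVL6 falling. GDF15 (1.99 ± 0.24), the sterol regulator INSIG1 (1.92 ± 0.17), MANF (1.86 ± 0.14), SLC17A5 (1.78 ± 0.14), HMGCS1 (1.77 ± 0.17), DNAJB9 (1.68 ± 0.14), the autophagy gene WIPI1 (1.67 ± 0.15) and SEC24D (1.67 ± 0.19) were among the 12 largest averages. The 12 lowest included FAM111B (-2.15 ± 0.16), H2BC14 (-1.88 ± 0.29), CHAC2 (-1.74 ± 0.16), UHRF1 (-1.71 ± 0.15), CLSPN (-1.70 ± 0.25), HELLS (-1.65 ± 0.22), CCNE2 (-1.62 ± 0.23) and EXO1 (-1.57 ± 0.19). In this contrast 1976 genes passed, 1028 higher and 948 lower (3249 with the run as a block). Called in 1 direction in all 3 lines were 28 genes higher, against 0.39 expected of independent lists, among them MANF, DNAJB9, EIF2AK3, COPA, LMAN1, IDI1, MSMO1, DHCR7 and OSBP, of which EIF2AK3, COPA, LMAN1, IDI1, DHCR7 and OSBP were chosen after their values were seen. The 3 genes lower in all 3 were CHAC2, TNFRSF12A and TYMS, against 0.14 expected. The call of TYMS in A549 was lost with the replicate block and when some 1 array was left out. TNFRSF12A was chosen after its values were seen. Genes shared by all 3 lines with the run as a block were 64 higher against 2.2 expected and 15 lower against 1.6. All expected counts of shared genes here are taken over all 17687 genes. Many of these are dim, with a median level of 6.481 against background probe sets up to 6.69, and may seldom be called. The expected counts may therefore be too low and the excess overstated. At least 2 lines shared the direction for 475 genes, 271 higher and 204 lower (1005 with the run as a block). H1975 and H1299 shared 221 higher genes against 42.9 expected (Fisher's exact test, p = 9.4e-101, genes not being independent replicates) and 199 lower against 50.1, while 62 against 44.5 expected were higher in H1975 and lower in H1299 (Fisher's exact test, p = 0.0089) and 36 against 48.3 the other way (p = 0.068). These opposite calls were, with the run as a block, 127 against 135 (Fisher's exact test, p = 0.45) and 92 against 135 (p = 3.1e-05), so the excess of the first was not kept. Across all genes, which are not independent, the fold changes had Pearson's r of 0.24 between H1975 and H1299, 0.11 between A549 and H1299, and 0.068 between H1975 and A549.

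The Omomyc effect differed between lines for 1446 genes by limma's moderated F test (3073 with the run as a block). SLC7A5 was at 1.25 ± 0.17 in H1975, -0.04 ± 0.20 in A549 and -3.26 ± 0.16 in H1299. DDIT3, at the level of background probe sets in H1975 PBS arrays, was at 4.61 ± 0.25, 1.35 ± 0.28 and -1.85 ± 0.23. In the same order SLC7A11 was at 2.01 ± 0.28, -0.41 ± 0.31 and -3.84 ± 0.26, and STC2 at 2.27 ± 0.23, 0.05 ± 0.27 and -2.74 ± 0.22. ALDH1L2 was at 2.41 ± 0.24, 1.36 ± 0.28 and -2.45 ± 0.23, and WARS1 at 0.86 ± 0.16, 1.47 ± 0.19 and -1.69 ± 0.15. IL24, SLITRK6, BMP4 and CASTOR2 completed the 10 genes with the smallest p, and CASTOR2 was at -2.70 ± 0.21, 0.18 ± 0.24 and 1.25 ± 0.20. GDF15, at 5.23 ± 0.40 in H1975, was at 0.73 ± 0.45 (adjusted p = 0.767) in A549 and 0.01 ± 0.38 (adjusted p = 0.994) in H1299. The ATF4 list differed between H1975 and H1299 by a median of 2.62 (camera adjusted p = 5.27e-59; adjusted p = 1.34e-05 and 4.97e-09 with an estimated correlation). The ER unfolded protein list rose more in A549 than in H1975, with a median of -1.22 for H1975 minus A549 (camera adjusted p = 2.46e-11; adjusted p = 0.032 and 4.43e-05 with an estimated correlation).

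**Figure D3:**
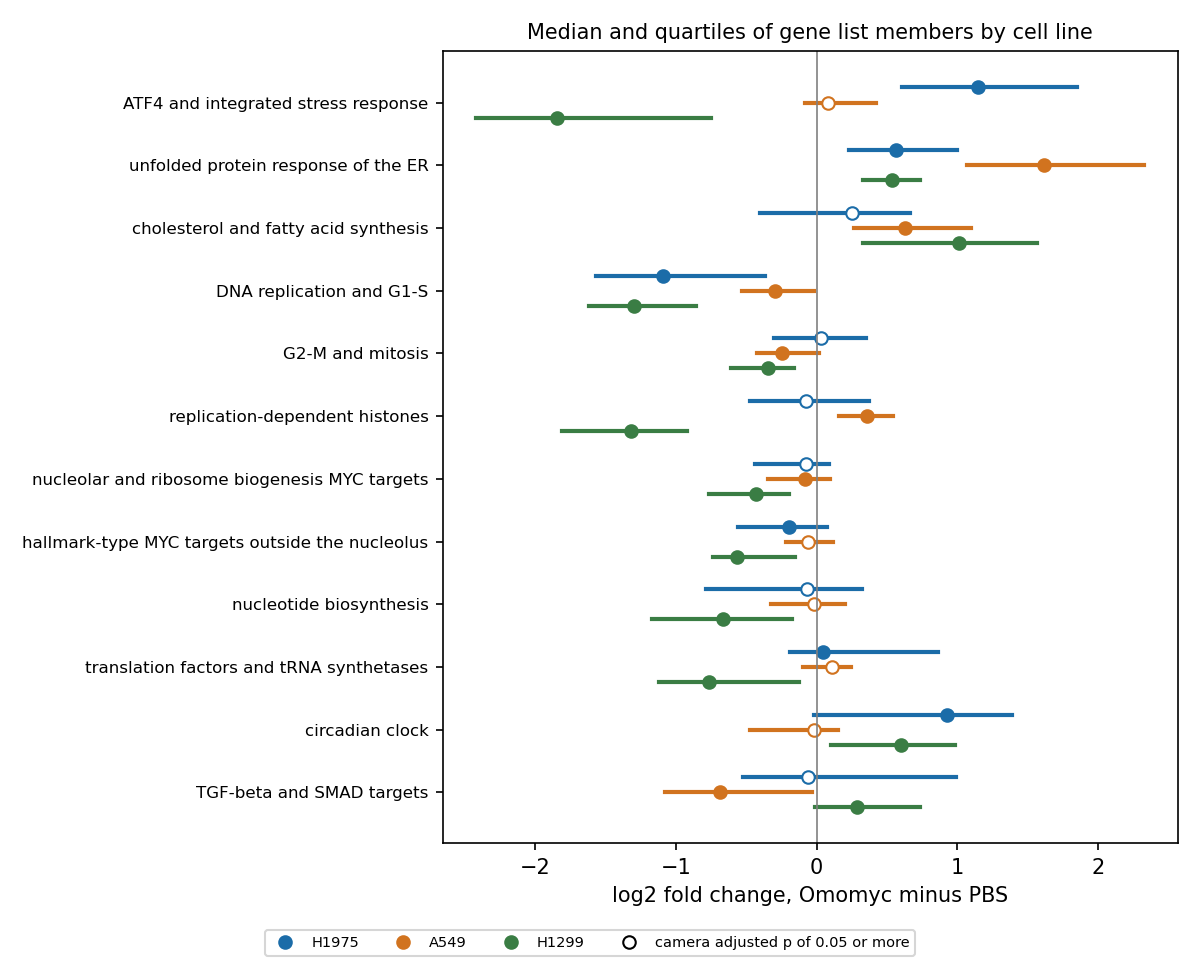
Median (points) and quartiles (lines) of the log2 fold changes, Omomyc minus PBS, of the members of 12 gene lists in the 3 lines. Filled points have a camera adjusted p under 0.05 at a preset correlation of 0.01, open points do not, and the ATF4 list medians were 1.15 in H1975 and -1.85 in H1299.

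With an estimated correlation, the list calls that held were those of the ATF4 list in H1975, of the ER unfolded protein list in A549, and of the ATF4, DNA replication, cholesterol, translation and ER unfolded protein lists in H1299. In all, 6, 7 and 15 list calls held in H1975, A549 and H1299 with the run as a block too. At the preset correlation, the run as a block ended the calls of lysosome genes in H1975 (adjusted p = 0.0752) and histones in A549 (adjusted p = 0.102). Besides that of nucleolar targets in H1975, it added those of ribosomal protein genes (adjusted p = 0.0378, 0.0848 without it) and the circadian clock (adjusted p = 0.0485) in A549. At the preset correlation, other groupings of the arrays gave up to 16 called lists in H1975, 18 in A549 and 20 in H1299, against 15, 14 and 19 with the labels. Those highest groupings had exchanged only 1 array or nearly mirror the labels, so they keep much of the treatment difference.

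Markers of other cell types gave no call shared by the lines. Leukocyte markers had camera adjusted p of 0.64, 0.741 and 0.312 in H1975, A549 and H1299, fibroblast markers 0.403, 0.95 and 0.878, and neuroendocrine markers 0.535, 0.741 and 0.533. Single members moved in H1975, where CD14 fell and CD68 rose by 1.49 ± 0.23. Of the fibroblast markers ACTA2 rose and S100A4 and FBLN1 fell in that line, FBLN1 losing the call when some 1 array was left out. Airway markers, called in A549 (0.0417), were at 0.322 and 0.892 in H1975 and H1299, epithelial genes at 0.859, 0.741 and 0.878, and mitochondrial respiratory chain genes at 0.64, 0.133 and 0.136.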

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

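The tests of the normalization runs, of the starting level and of the array apart were chosen only after the result was seen; the tests of other groupings, of scaling, of bright genes and of an added protein were written before.

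The ATF4 and integrated stress response list changed in opposite directions, and the list means differed between lines with an adjusted p of 1.08e-12. With the run as a block and an estimated correlation, the difference between H1975 and H1299 kept an adjusted p of 4.97e-09, with medians above 0 in every run of H1975 and below 0 in every run of H1299, which argues against the normalization runs as the cause. Quantile normalization and median centring left the median in H1975 minus the median in H1299 at 3.01 or more. The median log2 fold change over all genes was only 0.0038 in H1975 and 0.0018 in H1299, so these scalings could change little. That small size argues against a shift of whole arrays as the cause. A high starting level alone would predict a fall in A549 too, whose PBS arrays were at 11.36 against 11.17 in H1299, yet its list mean changed by 0.193. A549 is 1 line and changed less in general, with 211 called genes against 1569 in H1299, so a part of the starting level is not excluded. The list mean went from 8.707 to 9.95 in H1975 and from 11.17 to 9.529 in H1299, so these 2 lines drew closer. A biological origin in the cell lines remains a hypothesis, and which of the many features that differ between them would underlie it was not tested.

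The ER unfolded protein list rose in the 3 lines and differed in size between them (limma F test, adjusted p = 4.9e-06), though in H1975 its adjusted p was 0.0568 with an estimated correlation and 0.00042 with the run as a block too. Its lowest median within any run of any line was 0.391, against a cause in the runs. Its median exceeded 100% of 10000 random lists matched on mean level in each line, against a general rise of bright genes. The series has 0 arrays with another added protein, so an effect of Omomyc and a response to any protein at this dose cannot be told apart. This limit holds for every comparison with PBS here, not for this list alone.

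In A549, the immediate early list stood at 11.81 in PBS replicate 3 and between 8.914 and 9.258 in the other PBS arrays, a gap that marked it as apart. Without that array the mean log2 fold change of the list was -0.159 in place of -0.827, so the single array may account for most of the fall. The camera call of the list was kept without it (adjusted p = 0.00624, and adjusted p = 0.734 with an estimated correlation). The list median nearest 0 within a run was -0.275, in run 1, while run 2 had this array as its only PBS array. No biological explanation was tested, since the labels do not set this array apart.

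Among 265 checks for an array far from the others, 7 were marked, where chance marks about 1 in 20. Besides that list, they were metallothioneins in A549 PBS replicate 3 (10.27, others 9.043 to 9.193), the cholesterol list in H1975 PBS replicate 4 (10.24, others 10.71 to 10.76), the TGF-beta list in H1975 Omomyc replicate 5 (9.235, others 9.57 to 9.704), neuroendocrine markers in A549 PBS replicate 4 (5.67, others 5.779 to 5.795), MXD3 in H1975 Omomyc replicate 4 (7.784, others 6.266 to 6.683) and MNT in H1975 Omomyc replicate 3 (9.742, others 10.45 to 10.61). In 3 of these the only array of the other treatment in the same run and line was shifted alike, so the mark does not set 1 array apart. Metallothioneins were at 10.47 in A549 Omomyc replicate 3 (others 9.069 to 9.221), the cholesterol list at 10.51 in H1975 Omomyc replicate 5 (others 10.91 to 11.11), and the TGF-beta list at 9.024 in H1975 PBS replicate 4 (others 9.305 to 9.562).

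Of 35 list means, further ones whose Omomyc effect differed between lines (limma F test, adjusted p) were translation factors and tRNA synthetases (2.76e-05), genes described as repressed by MYC (0.00441), the circadian clock (0.00441), TGF-beta and SMAD targets (0.00441), replication-dependent histones (0.00442), MondoA targets (0.0185), DNA replication (0.0229), cholesterol synthesis (0.0264) and antigen presentation (0.0415). With the run as a block, 29 of the 35 differed, against 11 without it, which all differed with it too. Of the 28 single genes tested in this way, 10 (SLC7A5 and those after it) had been named for the smallest p of this same test, so that they differ follows from that choice. With them, the differing ones were MYC (2.07e-05), MAX (0.000944), MXD1 (0.000135), CDKN1A (0.0106), TXNIP (0.00995), CCND1 (5.65e-05), GDF15 (2.61e-07), SLC7A5 (1.2e-12), DDIT3 (1.56e-12), SLITRK6 (3.33e-11), IL24 (6.02e-11), SLC7A11 (7.4e-11), STC2 (7.4e-11), ALDH1L2 (8.66e-11), BMP4 (1.59e-10), WARS1 (2.46e-10) and CASTOR2 (4.22e-10).

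Features without a gene symbol also changed. Of 6548 tested, 502 passed in H1975, 45 in A549 and 328 in H1299, and 866, 102 and 660 with the run as a block.

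Other groupings of the arrays gave fewer called genes. In H1975 1 of 100 groupings, the real one with 2095, reached that count, and the next had 1411; it and 3 more with 639 to 1071 had exchanged all 4 PBS arrays, which nearly mirrors the labels. In A549 1 of 35 reached 211 and the next had 45, and in H1299 1 of 100 reached 1569 and the next had 498, with 4 of 5 arrays of 1 side from run 3, a structure of the runs. These groupings ignore the replicate numbers, which by the rule set beforehand pair the arrays of A549 and H1299. With the run removed no pair stayed over 0.1, so the numbers may mark only the shared run. Removing the run itself lowers correlations between arrays of that run, so this check cannot decide it. Groupings that part as many pairs as the labels number 8 in A549 and 16 in H1299, too few for a share under 0.05; there the highest count besides the real one was 3 and 2 genes. Joint regrouping gave at most 279 genes for the average (real 1976), 477 for the difference between lines (1446) and 26 for the overlap (475), each reached by 1 of 100. Over groupings that ignore the pairs, each of these 6 counts was reached by the real grouping alone. These shares were under 0.05 and not adjusted for the number of counts, and in A549 the smallest possible was 1 of 35. For gene lists in H1975 4 of 100 groupings gave at least 15, a share under 0.05, but the highest other gave 16, more than the labels. In A549 3 of 35 gave at least 14 (highest other 18), and in H1299 5 of 100 gave at least 19 (highest other 20). The other groupings that reached these list counts had exchanged only 1 array, or nearly mirror the labels. The mirrors exchanged 4 arrays in H1975 and H1299 and 3 in A549. All keep much of the treatment difference, so they are a poor stand-in for chance. This comparison therefore cannot exclude chance for the number of lists in any line, nor point to it.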

How the results depend on the processing

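The tests with the run as a block, single runs and combinations with them were chosen after seeing the data. Of 360 gene results and 48 list results, none changed direction past the threshold under any alternative computed for them. The list results were only those called in the main fit, and fits on single runs were computed for gene counts alone. Within single runs, the medians of the histone and nucleolar lists called in A549 differed in sign. Dim genes, near the background probe sets, limit the folds of genes such as IL24.

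Counts for H1975, A549, H1299, the average, the difference between lines and the overlap were 1194, 113, 886, 1084, 701 and 215 at the stricter adjusted p under 0.01. At an adjusted p under 0.05 and a fold change of at least 2, H1975 had 1244, H1299 804, the average 199 and the overlap 209. The run as a block gave 3400, 502, 2812, 3249, 3073 and 1005, and with the replicate block added H1975 had 1245 and H1299 2622; the cause was not tested. Quantile normalization gave 352 in A549, 2340 for the difference and 797 for the overlap, array weights 477 in A549, and a fit on A549 alone, with fewer arrays, 81; the cause was otherwise not tested. Runs alone, with fewer arrays, in part 1 against 1 with the spread of other groups, gave, for runs 1, 2 and 3, 1018, 1047 and 780 in H1975, 81 and 523 for runs 1 and 2 in H1299, and 50 and 44 for runs 1 and 2 in A549. An estimated correlation left 1, 1 and 5 lists in H1975, A549 and H1299 in place of 15, 14 and 19, and 6, 7 and 15 with the run as a block too. With fry, which does not compare a list with other genes, 9, 3 and 12 passed.

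The replicate block alone gave 2585, 226, 2239, 2404, 1925 and 649 genes, all within 1.5 times. It ended the list calls of hallmark-type MYC targets in H1975 (adjusted p = 0.0749, alternatives 0.00486 to 0.756), lysosome genes in H1975 (0.0853, alternatives 0.0226 to 0.756) and histones in A549 (0.512, alternatives 0.000187 to 0.825), and no other list call. Of the gene results 9 lost and 6 gained a call with it. In H1975 the numbers do not pair arrays by the correlation check, so its block says nothing of a weaker effect.

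Leaving out 1 array gave 1627 to 2112 genes in H1975, 128 to 188 in A549, 1272 to 1460 in H1299, 1651 to 2009 for the average, 1199 to 1474 for the difference, 383 to 491 for the overlap, and 11 to 17, 11 to 17 and 17 to 19 lists in the 3 lines. In A549, 128 was without Omomyc replicate 1 and 139 without PBS replicate 4.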

Other observations

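The tests of G1-S against G2-M genes, and the run as a block, were chosen only after the result was seen; the test of transport genes was set before, and its reading in H1975 and H1299 was changed after.

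Circadian clock genes were higher in H1975, where 10 of 18 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.93, camera adjusted p = 6.03e-05, adjusted p = 0.26 and 0.0192 with an estimated correlation), and in H1299, where 6 rose (8 and 0 adjusted over the list alone, median 0.60, camera adjusted p = 6.12e-06, adjusted p = 0.0927 and 0.00403 with an estimated correlation), and had 0 rising members in A549 (0 and 2 adjusted over the list alone, median -0.021, camera adjusted p = 0.0542, adjusted p = 0.666 and 0.131 with an estimated correlation). BHLHE40, a clock-linked repressor gene, rose by 3.17 ± 0.31 in H1975 and 2.57 ± 0.29 in H1299, NR1D1 by 2.56 ± 0.29 in H1975, and BMAL1 fell (-1.25 ± 0.26). Lysosome and autophagy genes had 8, 1 and 9 rising of 42 in H1975, A549 and H1299, with medians of 0.11, 0.33 and 0.32 and adjusted p of 0.0443, 0.00244 and 4.04e-06 (8, 2 and 12 rose adjusted over the list alone, adjusted p = 0.756, 0.666 and 0.216 with an estimated correlation, and 0.249, 0.0397 and 0.00316 with the run as a block too). The protease gene CTSL rose by 2.58 ± 0.20 and the cholesterol export gene NPC1 by 2.27 ± 0.20 in H1975. The lysosome call in H1975 was lost with the replicate block (adjusted p = 0.0853), with the run as a block (adjusted p = 0.0752) and without PBS replicate 3 (adjusted p = 0.0578), PBS replicate 4 (0.0511), Omomyc replicate 1 (0.105), Omomyc replicate 2 (0.0547) or Omomyc replicate 4 (0.0509).

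Lists of immune genes were called upward in H1299. Antigen presentation genes had 6 of 20 rising and 1 falling (8 and 1 adjusted over the list alone, median 0.53, camera adjusted p = 0.00141, adjusted p = 0.216 and 0.0213 with an estimated correlation), HLA-E at 1.16 ± 0.20, B2M at 0.89 ± 0.20, while the checkpoint ligand gene CD274 fell (-1.12 ± 0.20). Interferon genes had 5 of 38 rising (6 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 0.00505, adjusted p = 0.469 and 0.00778 with an estimated correlation), IFITM1 at 1.78 ± 0.23, against adjusted p of 0.138 in H1975 and 0.126 in A549. NF-kB genes were called in H1975 (7 rose and 2 fell; 9 and 3 adjusted over the list alone, median 0.38, camera adjusted p = 0.00652, adjusted p = 0.555 and 0.0627 with an estimated correlation) and H1299 (6 rose; 7 and 1 adjusted over the list alone, median 0.17, camera adjusted p = 0.00458, adjusted p = 0.395 and 0.0488 with an estimated correlation). TGF-beta targets had 5 rising in H1299 (7 and 1 adjusted over the list alone, median 0.28, camera adjusted p = 0.0126, adjusted p = 0.433 and 0.0415 with an estimated correlation) and an adjusted p of 0.403 in H1975. MondoA targets had 1 falling in A549 (1 and 4 adjusted over the list alone, median -0.39, camera adjusted p = 0.00149, adjusted p = 0.367 and 0.00598 with an estimated correlation) and 3 rising in H1299 (4 and 0 adjusted over the list alone, median 0.30, camera adjusted p = 0.0141, adjusted p = 0.385 and 0.0213 with an estimated correlation). Metallothioneins had 1 rising member in H1975 (1 and 0 adjusted over the list alone, median 0.53, camera adjusted p = 0.0425, adjusted p = 0.642 and 0.385 with an estimated correlation) and 1 in H1299 (1 and 0 adjusted over the list alone, median 0.41, camera adjusted p = 0.0251, adjusted p = 0.433 and 0.316 with an estimated correlation). NRF2 targets had 4 rising and 1 falling in H1299 (6 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 0.0483, adjusted p = 0.623 and 0.189 with an estimated correlation). In H1975 the NRF2 list was not called (median -0.275), and its members passed in both directions. AKR1C3 was at -2.30 ± 0.22 and AKR1C2 at -1.89 ± 0.26 there, while SLC7A11 and FTL rose. Immediate early genes in H1975 had 5 rising and 2 falling (10 and 4 adjusted over the list alone, median 0.50, camera adjusted p = 0.0286, adjusted p = 0.756 and 0.484 with an estimated correlation). The p53 targets had adjusted p of 0.597, 0.0848 and 0.715 in the 3 lines, and apoptosis regulators 0.114, 0.266 and 0.878. Leaving out 1 array ended calls in H1975 for immediate early genes without Omomyc replicate 2 (adjusted p = 0.0547) or Omomyc replicate 5 (0.0545) and for metallothioneins without PBS replicate 1 (adjusted p = 0.0686), PBS replicate 3 (0.0863), Omomyc replicate 2 (0.0814) or Omomyc replicate 5 (0.0615). In H1299 it ended those of metallothioneins without PBS replicate 2 (adjusted p = 0.112), TGF-beta targets without PBS replicate 4 (adjusted p = 0.062) and NRF2 targets without PBS replicate 1 (adjusted p = 0.0903), PBS replicate 4 (0.0811), PBS replicate 5 (0.063), Omomyc replicate 2 (0.0792), Omomyc replicate 3 (0.0559), Omomyc replicate 4 (0.0701) or Omomyc replicate 5 (0.0611).

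A hypothesis is that Omomyc lowered G1-S genes more than mitotic genes. The mean of the DNA replication list minus that of the G2-M list was -1.75 ± 0.119 (SD, n = 4) in PBS and -2.85 ± 0.108 (n = 5) in Omomyc arrays of H1975, a difference of -1.1 (two-sided exact permutation p = 0.00794, 0.0119 adjusted over the 3 lines). In H1299 the difference was -0.827 (exact permutation p = 0.00794, the smallest possible in H1299 and in H1975, 0.0119 adjusted), and in A549 it was -0.0365 (exact permutation p = 0.771). Within runs it was -1.26, -0.902 and -1.28 in H1975, -0.143 and 0.0842 in A549, and -0.988, -0.785 and -0.789 in H1299. The numbers pair the arrays of H1299 by the rule set beforehand, though not with the run removed. Exchange within these 5 pairs gave an exact permutation p of 0.0625, the smallest possible. The call in H1299 therefore rests on exchange over all arrays. The hypothesis came from the medians of the same lists on the same arrays, so these p-values restate that difference and add no support of their own. In A549 the standard error was 0.082, so a difference as large as that of H1299 lay outside 2 standard errors. This bound replaced a p over the threshold as the criterion after the result was seen. Cell-cycle phases were not measured.

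Several of the 28 genes higher in all 3 lines serve transport between ER and Golgi, which suggested that this class may rise as a whole. Of 76 listed transport genes 68 were measured, and the 54 named nowhere else were tested. In A549 the median was 0.534, 8 rose and 0 fell (camera with an estimated correlation, adjusted p = 0.00999 over the 3 lines). In H1975 the median was 0.24 with 4 rising and 0 falling (adjusted p = 0.153), and in H1299 0.222 with 11 rising and 0 falling (adjusted p = 0.14). Both missed the threshold, as did the unadjusted p that the criterion named (0.153 and 0.0933, by camera over 54 genes), and the criterion set beforehand would have counted that against the hypothesis. That criterion was given up after the result was seen, since a p over the threshold excludes no rise. With the run as a block, camera gave adjusted p = 0.0132 in H1975, adjusted p = 0.00575 in H1299 and adjusted p = 1.71e-05 in A549. The criterion was met in A549, and the hypothesis stays open in H1975 and H1299. The idea came from genes called on these same arrays, so the test of the 54 genes is not independent support.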
